A study of Mus musculus with 2 samples.

How the data were processed

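Splenic B cells of C57BL/6 mice, taken at steady state or 6 days after antibody blockade of the inhibitory receptor PD-1 (anti-PD1), were sorted into plates of 384 wells. Transcripts were captured with oligo-dT primers that carried cell barcodes and unique molecular identifiers (UMIs, tags that mark each captured molecule). The cDNA was then amplified by nested PCR with primers for about 500 genes, per the labels' protocols. The series held 2 samples, which were 2 experiments, and each contained cells of both conditions. Per the submitters' processing notes, bcl2fastq, Bowtie2 2.2.9, HTSeq, Seurat 3.2.3 and the mouse genome build GRCm38.p6 were used, and their roles were not given in the sources used here. The reads and UMI tables were not used here.

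The deposited table gave 456 genes in 1047 cells, with each cell's experiment, plate, well, mouse, condition and sort label, and 1047 was also the number of cells the labels stated. The values were a score: whole numbers that the authors had normalized and rounded by a method not given in the sources used here. The rounding and scaling were read from the values. Each sort label had its own narrow range of totals per cell on every plate, and 98.0% of the variance of the log2 totals lay between labels. In 23 cells the smallest nonzero value was 2. The depth behind each value was therefore unknown, and differences in total RNA between labels could not be read from the table. No count model was used. Of the 456 gene names, 451 matched a current mouse symbol and 3 matched a synonym. The other 2, Il4r1 and Ubec2c, matched none and keep their deposited names. Coordinates are those of RefSeq genes on GRCm38.p6. The deposited values were 82.6% zeros, and 1 gene was listed at 0 in every cell. No column of values was left without a sample.

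The planned scale was the authors' normalization, with rescaling as its alternative. The 2 were exchanged after the totals were seen to follow the sort label and before any test was run. Each cell was rescaled to a common total of 255, the median over cells. The rescaled values were taken as log2(value + 1) and averaged over the cells of each mouse, condition and class. The median difference of all tested genes on this scale and on the deposited scale was 0.04 and 0.14 for GC cells between conditions, 0.01 and 0.20 for plasma cells between conditions, 0.11 and 0.27 for GC against naive cells, 0.06 and 0.31 for plasma against naive cells, and −0.07 and 0.02 for plasma against GC cells. Differences are on the log2(value + 1) scale, which understates the change of genes at low values. Shares of the panel total (a gene's percentage of all deposited units of a cell, averaged over the cells of a mouse) are given beside them. A difference averages logs over cells, so it can also exceed the change of the shares or go against it. H2-K1, chosen after its values were seen, took 14.3% in anti-PD1 IgG1 plasma cells and 15.5% in 11 steady-state ones, with a difference of 0.28. Rescaling does not remove the coarser rounding of labels with low totals. A mouse entered with at least 10 cells of a class, and a cell needed at least 10 genes with a nonzero value, which all 1047 cells met. Genes had a nonzero value in at least 10% of the cells of a compared group.

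The 17 averages of 7 groups of cells were fitted in 1 model with limma 3.58.1 (lmFit and eBayes, R 4.3.3) and the experiment as a block, with 9 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with fry and camera in the same fit. Camera was run with its preset correlation between genes and again with an estimated one, with statmod 1.5.0 installed for the random block. The fry test asks whether the members of a list move one way on balance and does not compare the list with other genes. The lists were fixed before the data were examined: markers of naive, germinal center, plasma and memory B cells, of T cells, of myeloid cells, granulocytes or basophils, of NK or innate lymphoid cells and of erythroid cells; the sort gate and the immunoglobulin heavy constant genes; and proliferation, dark zone, light zone and activation, survival and apoptosis, secretion and the unfolded protein response, interferon response, checkpoint and costimulation, chemokine and trafficking receptors, cytokines and their receptors, B cell receptor signalling, B cell transcription factors, MHC class II presentation, and housekeeping and RNA quality. The panel held 0 members of the erythroid and immunoglobulin lists.

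Germinal center (GC) and plasma cells were sorted into separate plates, naive cells lay on all 8 plates, and the conditions held different wells of a plate. The labels state 4 mice per condition. The table named 7 mice, 3 with anti-PD1 and 4 at steady state, and the anti-PD1 mouse of experiment 1 had cells on both plates of each kind. The mouse was the replicate, so p-values measure the spread between averages of mice. This spread was pooled for each gene over all 7 groups of cells, and not taken from the compared groups alone. Naive, germinal center and plasma cells of the anti-PD1 mice came from the same animals. The correlation of a mouse's averages across classes, estimated as a random block, was 0.0018. The comparisons of classes within the same mice and the interaction were also fitted with the mouse as a fixed block, the paired form, with 5 residual degrees of freedom.

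Genes named in the text followed a rule set at the same time as the lists. It took up to 15 called genes higher and 15 lower per comparison by the size of the difference, up to 4 called members per list, and Pdcd1, which encodes PD-1 and was not on the panel, with its ligands Cd274 and Pdcd1lg2 whatever their values. These genes also had to be nonzero in at least 10% of cells of a compared group in each experiment that held both groups. Genes named outside the rule are marked as chosen after their values were seen.

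Clusters were made from the scaled log values of the 416 genes nonzero in at least 1% of cells (scanpy 1.11.5, leidenalg 0.10.2, Leiden resolution 0.5, seed 0). The 20 principal components and 15 neighbours were chosen after the totals were seen. Classes came from the deposited sort labels and not from clusters. Doublets were not called, since cells were sorted singly and raw UMI totals were not used here. Tables were handled with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 under Python 3.11.15, and plots with matplotlib 3.10.9. Intervals on shares of cells are exact binomial intervals at 95% and cover counting error only.

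The calling of genes was tested on simulated data with the cells' own totals, whole-number values and a spread between mice set to match the real residuals. The deposited totals stood in for the unknown depth, and no differences between experiments or plates were simulated. Changed genes were drawn from those with larger shares of the panel total. The rates below hold for such data only. In 20 simulations of each comparison without any change, the median number of false calls was at most 1 on the common total, and the highest was 9, in plasma cells against naive cells. On the deposited scale the same simulations gave a median of 2 false higher calls for germinal center cells between conditions and of 154.5 for plasma cells between conditions. With 60 genes changed, 4-fold changes were recovered in 28.25% of cases for germinal center cells between conditions and in 34.25% for plasma cells between conditions. They were recovered in 40.9% for germinal center against naive cells, 41.9% for plasma against naive cells and 32.25% for plasma against germinal center cells. Changes of 2-fold were recovered in 2.5%, 7%, 8.82%, 9.5% and 6.25% of cases in the same order, and no changed gene was called in the wrong direction. For plasma cells between conditions, simulations without any change gave at most 2 false higher calls. Dividing the same real averages by experiment gave 14 calls, so the simulations may understate false calls there.

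The alternatives planned with the lists were the deposited scale (planned as the main scale), the log2 of the mean value, a pseudocount of 0.1, no filter on low values, cells with at least 30 genes, the share of cells with a nonzero value, no experiment block, leaving out each experiment, lists without their leading member, and other settings of the clusters. Added after the totals were seen were thinning of every cell to 55 units (the lowest total of any cell), thinning of the germinal center cells to 173 units, a random block for the mouse, averages per plate with the plate as a block, weights by number of cells, only the compared groups in the fit, the anti-PD1 mouse of experiment 1 split by plate letter, leaving out each mouse, and steady-state plasma cells of any isotype. The fixed block for the mouse was added last, after the results of all other tests were seen.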

Results

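The study asked how blockade of PD-1, an inhibitory receptor best known on T cells, bears on B cell responses in the spleen. Targeted single-cell RNA sequencing measured 456 genes in 1047 sorted B cells of 7 mice in 2 experiments, of 564 and 483 cells. The sort separated naive B cells, germinal center (GC) B cells, which proliferate and mutate their antibody genes, and plasma cells, which secrete antibody. IgG1 is the antibody class by which GC and plasma cells were labelled. Anti-PD1 mice gave 300 IgG1 GC cells, 180 IgG1 plasma cells and all 158 naive cells. Steady-state mice gave 248 IgG1 GC cells, 75 GC cells that were not IgG1, 17 IgG1 plasma cells and 69 plasma cells that were not IgG1. The deposited values summed to 55 to 102 units per naive cell and to 556 to 770 units per IgG1 plasma cell of anti-PD1 mice. IgG1 GC cells summed to 295 to 422 units with anti-PD1 and to 173 to 260 units at steady state. These totals were set by the authors' normalization, the sequencing depth was unknown, and every comparison used cells rescaled to a common total of 255 units.

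**Figure D1:**
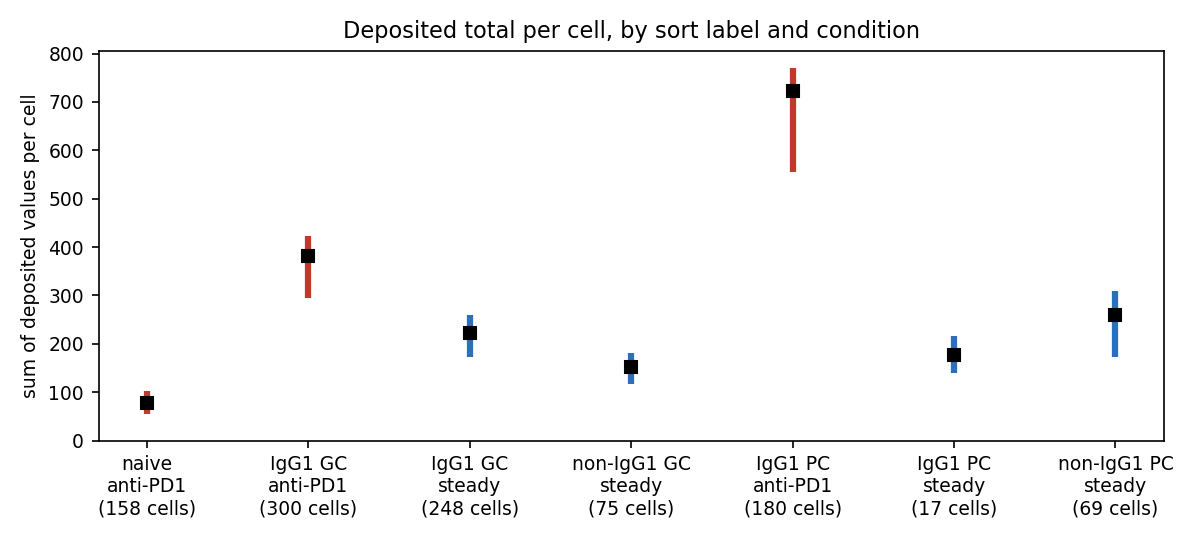
Sum of the deposited values per cell (vertical axis, deposited units), by sort label and condition (horizontal axis); squares are medians over cells, and bars run from the lowest to the highest cell. Totals fell in a narrow band per label, from 55 to 102 in naive cells to 556 to 770 in IgG1 plasma cells of anti-PD1 mice.

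IgG1 GC cells differed from naive cells of the same 3 anti-PD1 mice by genes of cell division and of the GC program. Cd24a, the heat-stable antigen (chromosome 10, 43579169 to 43584265), held 7.10% ± 2.50 (SD, n = 3) of the panel total in GC cells and 2.15% ± 0.965 (SD, n = 3) in naive cells. Its difference was 2.38 ± 0.20 (SE) on the log2 scale, with limma's adjusted p = 1.32e-05. Mcm2, a subunit of the replicative helicase (chromosome 6, 88883474 to 88898780), was higher by 1.43 ± 0.11 (SE), and Top2a, the DNA topoisomerase of dividing cells, took 1.46% ± 0.453 against 0.0888% ± 0.0171 (SD, n = 3 each). Aicda, the deaminase that mutates antibody genes (chromosome 6, 122553809 to 122564180), took 0.714% ± 0.314 against 0.0383% ± 0.0366 (SD, n = 3 each), and Bcl6, the repressor that GC B cells require (chromosome 16, 23965050 to 23988866), 1.06% ± 0.204 against 0.348% ± 0.218. Sell, the L-selectin by which cells enter lymph nodes (chromosome 1, 164061987 to 164082930), fell to 0.0289% ± 0.00848 from 0.814% ± 0.107 (SD, n = 3 each).

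In all, 60 genes were higher and 6 lower in GC cells among 256 tested. Over all 256 genes, the 3 GC values lay above the 3 naive values in 97 and below in 8. Chance gives 10% of genes in either direction, but only where genes enter alike through both groups. The filter on nonzero values was met by 254 genes in GC cells and 106 in naive cells. Most genes thus entered through GC cells alone, and these counts cannot be set against the 10%. Of the proliferation list, 5 of 6 tested members were higher and 0 lower, and 6 were when adjusted over the list alone. Mki67, a marker of cycling cells, differed by 1.62, and Pcna, the sliding clamp of replication, by 1.57. Of the GC markers, 5 of 7 were higher, among them the transcriptional coactivator Pou2af1 (1.62) and the death receptor Fas, which was listed at 0 in naive cells. With deposited totals of 55 to 102 units in naive cells, a listed 0 may hide a low value. Of 26 B cell transcription factors, 8 were higher and 0 lower, with Bach2 at 0.78 and Id3 at 0.46. The lists of naive markers (9 tested) and of chemokine and trafficking receptors (11 tested) each had the same 3 members lower, the homing and egress receptors Sell, Ccr7 (−0.43) and S1pr1 (−0.28). The naive list also had 2 members higher, Bach2 and Tnfrsf13c, the latter at −0.22 with the log2 of the mean value. The trafficking list had 1 member higher, Itgb1, and its median was 0.01 while its mean was −0.10. Among 29 cytokines and receptors, 8 were higher and 1 lower, and Il10 differed by 0.54. Adjusted over the list alone, these counts were the same except 15 higher and 2 lower cytokines and receptors. Fry passed 10 of 19 lists, with adjusted p = 1.76e-05 for proliferation and 3.06e-07 for GC markers. With an estimated correlation, camera's adjusted p was 0.156 and 0.231 for these, and 0.0423 for each of the naive and trafficking lists, the only 2 it passed. Fry passed these 2 as lower (adjusted p = 0.0134 each) on the common total but as higher on the share of cells with a nonzero value, which rises with a label's deposited total (0.00374 and 0.0232), and without its leading member the trafficking list was at 0.513. With the mouse as a block, the paired form of the comparison, Tnfrsf13c and Itgb1 lost the call (adjusted p = 0.0611 and 0.0991), and fry's adjusted p for the trafficking list was 0.141. The housekeeping and RNA quality list, of which only Actb (chosen after its values were seen) and Ptprc were tested, also passed fry (higher, adjusted p = 0.0194, and 0.0689 with the mouse as a block), with Ptprc called and camera's adjusted p = 0.907 with an estimated correlation. H2-K1, a class I MHC chain, was lower by −1.12 ± 0.29 (SE) on the common total and higher by 0.78 on the deposited scale. H2-Ab1, a class II chain, was the 1 of 8 class II members that was higher (1.41), while H2-Aa, chosen after its values were seen, was at −0.13 with adjusted p = 0.780. The split of calls was 148 higher and 1 lower on the deposited scale, 26 and 14 with the log2 of the mean value and 17 and 9 with cells thinned to 55 units. The number of calls was 34, 22 and 35 without the anti-PD1 mouse of experiment 1 and mice 1 and 2 of experiment 2, 33 without experiment 1 and 0 without experiment 2, where 1 residual degree of freedom was left.

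**Figure D2:**
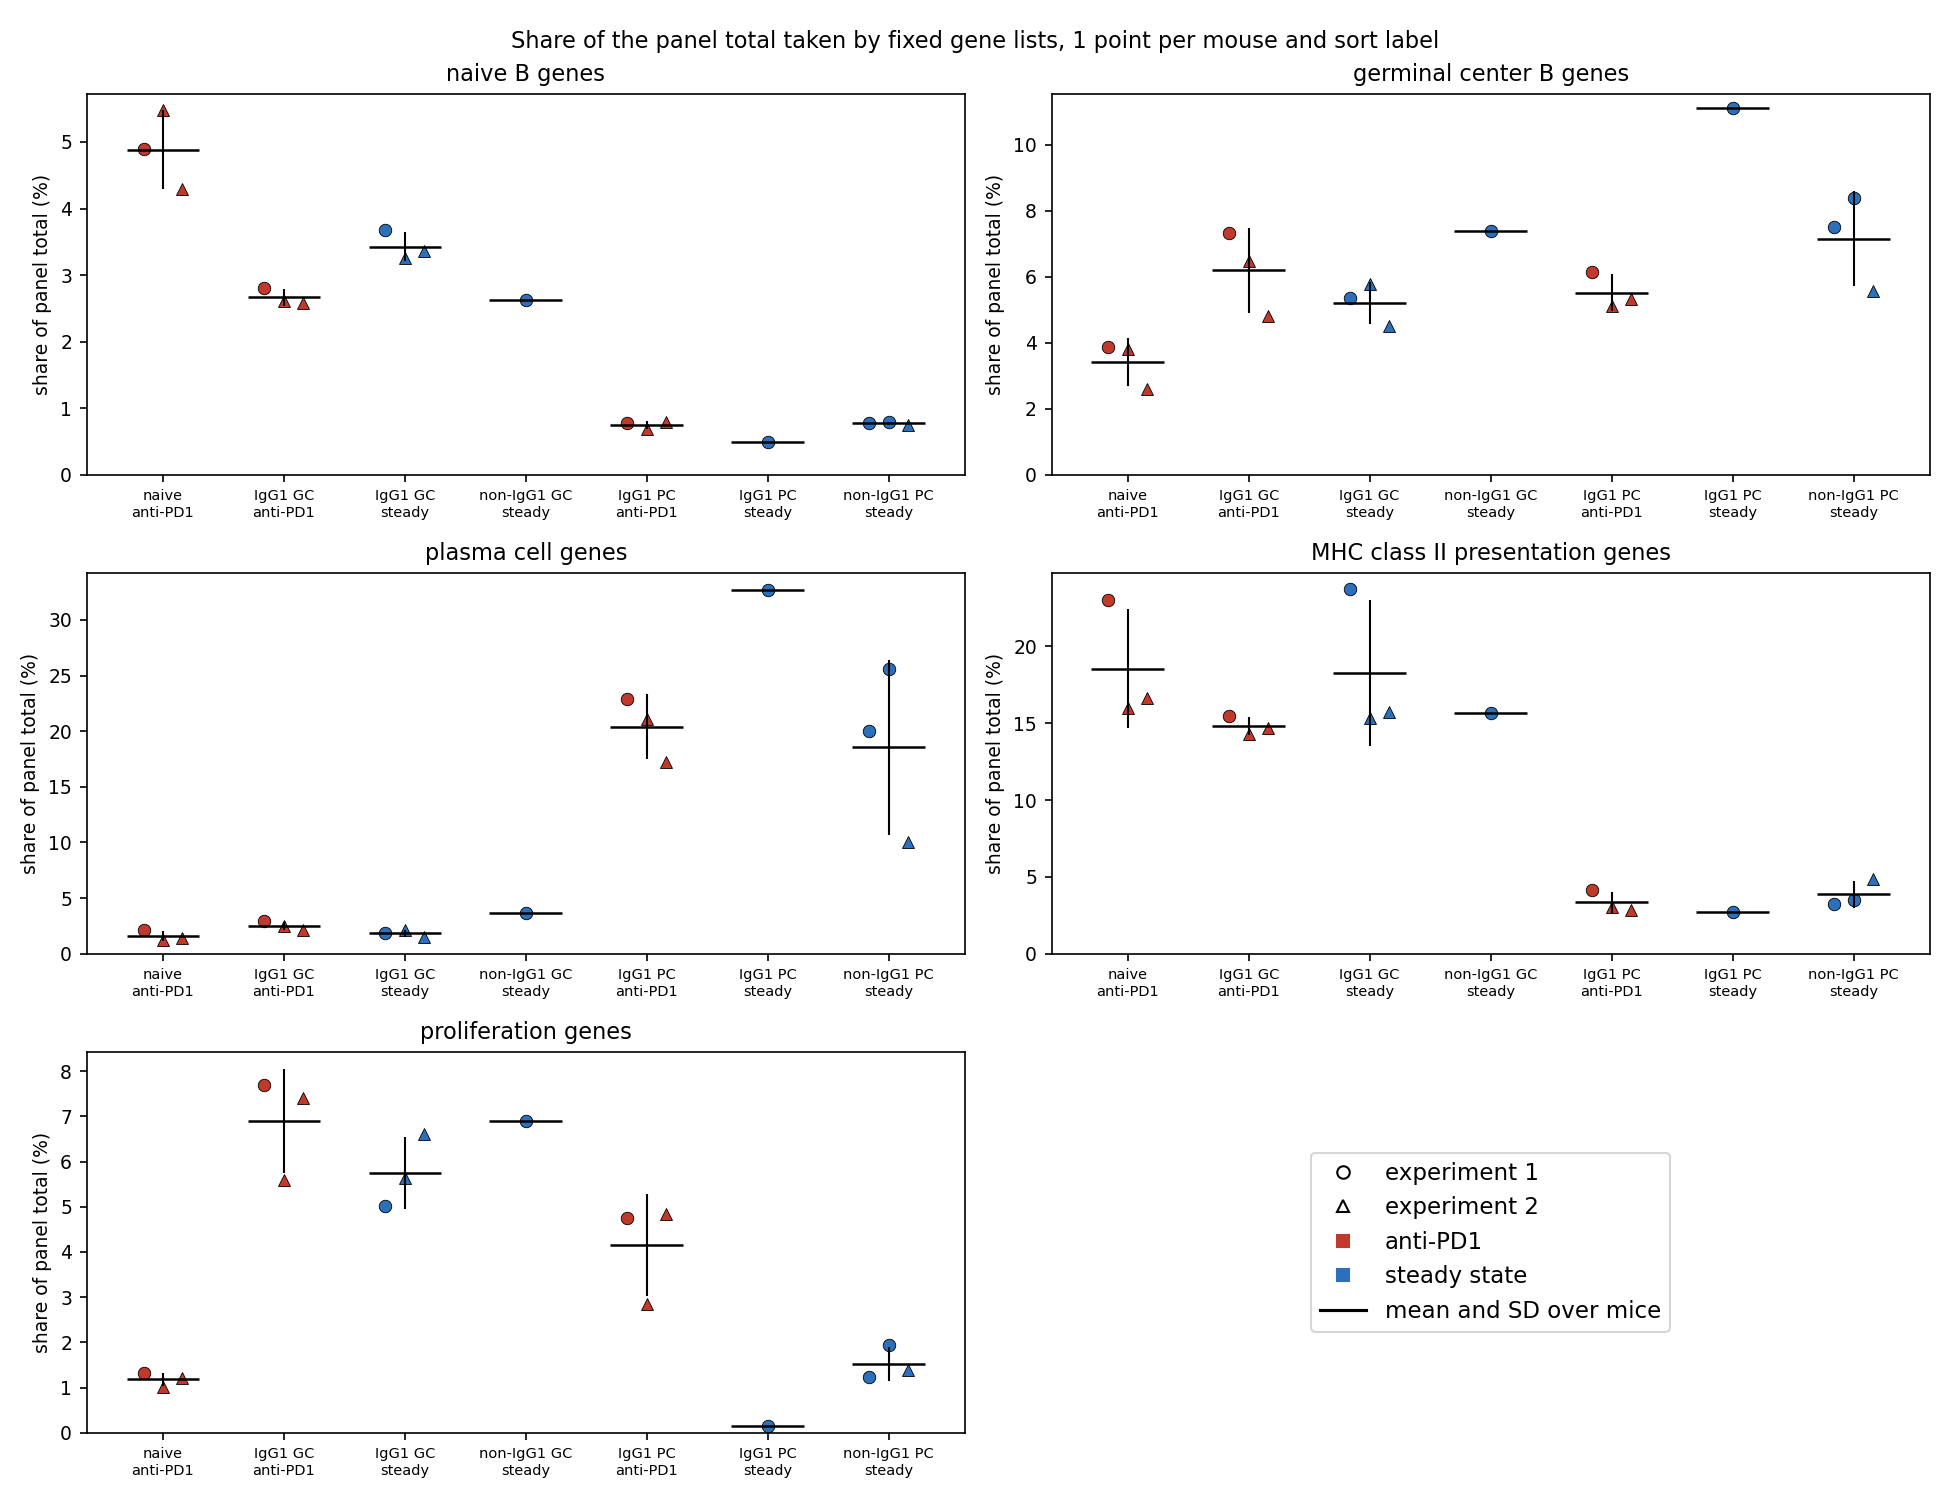
Share of the panel total (vertical axis, percent) taken by the naive, germinal center, plasma cell, MHC class II and proliferation lists in each group of cells (horizontal axis); points are mice with at least 10 cells (circles experiment 1, triangles experiment 2), and lines are the mean with SD where a group has 3 mice. Proliferation genes held 6.90% in IgG1 GC cells of anti-PD1 mice and 1.18% in naive cells, and class II genes 3.34% in their IgG1 plasma cells.

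IgG1 plasma cells of the anti-PD1 mice differed from naive cells by higher Mzb1, Xbp1 and Spcs1 and lower H2-Aa, Sell and Pax5. Mzb1, a chaperone of antibody assembly in the endoplasmic reticulum (chromosome 18, 35647265 to 35650266), held 16.1% ± 1.82 of the panel total against 0.813% ± 0.404 (SD, n = 3 each), a difference of 4.42 ± 0.22 (SE) with limma's adjusted p = 1.26e-07. Xbp1, a transcription factor of the secretory program (chromosome 11, 5520641 to 5525993), was higher by 1.47 ± 0.32 (SE), and Spcs1, a subunit of the signal peptidase, by 1.66 ± 0.20 (SE). H2-Aa, an MHC class II chain (chromosome 17, 34282744 to 34287823), fell to 0.697% ± 0.211 from 6.64% ± 1.98 (SD, n = 3 each). Sell was at 0.00786% ± 0.00805 against 0.814% ± 0.107 (SD, n = 3 each), and Pax5, a B cell identity factor, was lower by −0.56 ± 0.10 (SE).

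Among 255 genes, 52 were higher and 28 lower. All 80, called from these same averages, had the same direction in both experiments. Over all 255 genes the 3 plasma cell values lay above the 3 naive values in 94 and below in 32. The filter was met by 246 genes in plasma cells and 106 in naive cells. Most genes thus entered through plasma cells alone, and the 10% that chance gives in either direction does not hold for them. Of 14 plasma cell markers, 8 were higher and 0 lower, including Ell2 (0.84), an elongation factor used in antibody secretion, and Slpi, a protease inhibitor listed at 0 in naive cells, where a listed 0 may hide a low value. Of 5 secretion and unfolded protein response genes, 3 were higher, Xbp1, Edem1 (0.61) and Ern1 (0.17), and of 6 proliferation genes, 5 were higher, with Mki67 at 1.30. Of 8 naive markers, 5 were lower, 1 of which, Tnfrsf13c, was higher by 0.57 on the deposited scale, and of 9 trafficking receptors, 4 were lower, including Ccr7 (−0.51) and Cxcr5 (−0.37). Of 7 class II genes, 4 were lower and 1, the class II transactivator Ciita, was higher (0.48). Cd74 (−1.94) and H2-DMb2 (−1.48) were among the lower class II genes on the common total, and both were higher on the deposited scale, by 0.23 and 0.088. The antigen receptor chains Cd79a (−1.52) and Cd79b (−1.07) were lower on the common total and higher on the deposited scale, by 0.031 and 0.65. Cd79b is also on the list of sort gate genes, so the sort itself may set it apart. The B cell receptor list had 3 of 6 members lower and 2 higher. The transcription factors had 4 of 22 higher, among them Irf4 (0.60), and 6 lower, among them Bach2 (−0.60). Adjusted over the list alone, these counts were the same except 5 lower class II genes and 5 higher transcription factors. Fry passed 11 of 21 lists, with adjusted p = 0.000497 for plasma cell markers and 0.000485 for class II genes. With an estimated correlation camera's adjusted p was 0.370 and 0.118 for these, and 0.0327 for naive markers, the only list it passed. On the share of cells with a nonzero value, which rises with a label's deposited total, fry passed the B cell receptor and the housekeeping list as higher (adjusted p = 0.000482 and 0.000198), and class II genes, naive markers and trafficking receptors were higher without passing (0.0596, 0.296 and 0.0504). The 2 tested housekeeping and RNA quality genes passed fry as lower (adjusted p = 0.0371, and 0.0569 with the mouse as a block), although their median was 0.05, with Ptprc lower (0.069 on the deposited scale) and Actb (chosen after its values were seen) not called, and camera's adjusted p was 0.641 with an estimated correlation. No called gene belonged to the memory B, T cell or myeloid lists, of which 1, 5 and 2 members were tested, and Gzma, a granzyme, was the 1 tested NK or innate lymphoid marker and was higher (fry's adjusted p for this list was 0.0109, and 0.0576 with the mouse as a block). Fry also passed the GC markers as higher in plasma than in naive cells (adjusted p = 0.0102), but not without their member of the largest difference (0.281). The split was 169 higher and 3 lower on the deposited scale, 31 and 43 with the log2 of the mean value and 15 and 30 after thinning. Without the anti-PD1 mouse of experiment 1 and mice 1 and 2 of experiment 2 the calls were 37, 53 and 53, and they were 0 without experiment 2.

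Set against IgG1 GC cells of the same mice, IgG1 plasma cells had higher Mzb1 and Xbp1 and lower Bcl6, Bach2, Aicda and H2-Aa. Bcl6 held 0.0122% ± 0.0135 of the panel total in plasma cells and 1.06% ± 0.204 in GC cells (SD, n = 3 each), a difference of −1.41 ± 0.08 (SE) with limma's adjusted p = 1.1e-06. Bach2, which restrains plasma cell formation (chromosome 4, 32238413 to 32586109), was lower by −1.38 ± 0.09 (SE), and Aicda by −1.13 ± 0.13 (SE). H2-K1 held 14.3% ± 0.618 against 3.79% ± 0.455 (SD, n = 3 each), and Mzb1 was higher by 3.22 ± 0.22 (SE). The helicase genes Mcm2 (−1.10) and Mcm4 (−1.28) were lower in plasma cells.

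Of 296 genes, 31 were higher and 63 lower in plasma cells. All 94, called from these same averages, had the same direction in both experiments. Of 15 plasma cell markers 7 were higher and 0 lower, and of 8 class II genes 5 were lower and 0 higher, led by H2-Aa (−2.24) and H2-Ab1 (−2.23). The B cell receptor list had 4 of 7 lower, the sort gate genes 2 of 3 lower (Cd79b and Cd19), and the transcription factors 9 of 27 lower and 3 higher, among them Irf4 (0.64). The classes were made by the sort, so the sort gate genes are no independent test. Of 7 GC markers 3 were lower and 1, Polh, was higher by 1.03, a direction that turned with averages per plate (−0.0097), and fry passed the list as lower (adjusted p = 8.06e-06; camera 0.657 with an estimated correlation). The proliferation list had 2 of 6 lower, Mcm2 and Top2a (−0.73), with fry's adjusted p = 0.00531, or 0.0957 without its member of the largest difference and 0.206 on the share of cells, and camera's adjusted p = 0.728 with an estimated correlation. Of 5 secretion genes 1 was higher, Xbp1 (1.37), or 3 when adjusted over the list alone. The checkpoint list had 3 of 10 lower. Light zone and activation genes had 2 higher and 3 lower of 14, dark zone genes 1 and 1 of 4, and survival and interferon genes 1 lower each of 3 and 4. Ptprc, which encodes CD45, was the 1 of 2 housekeeping and RNA quality genes that was lower (−0.84). Fry passed this list as lower (adjusted p = 0.000359, and camera 0.749 with an estimated correlation). Without its member of the largest difference the list was higher and did not pass (fry's adjusted p = 0.134). Among 41 cytokines and receptors, 5 were higher and 10 lower. Adjusted over the list alone, 8 plasma cell markers were higher and 10 transcription factors lower, 4 light zone genes were higher and 4 lower, 2 survival genes were lower, and 6 cytokines and receptors were higher and 11 lower. Fry passed 14 of 21 lists, with adjusted p = 7.7e-05 for class II genes, and camera with an estimated correlation passed 0, with adjusted p = 0.451 for class II genes and for plasma cell markers. With the mouse as a block, fry's adjusted p was 0.101 for survival genes, 0.0852 for cytokines and receptors and 0.0852 for the NK or innate lymphoid marker Gzma, which had all passed, and Gzma itself lost the call (adjusted p = 0.0737). GC and plasma cells lay on different plates, and with the plate as a block 22 genes were higher and 32 lower, 45 of the 94 among them. As 0 plates held both groups, that fit compared them only through the naive cells on each plate. The plasma cell plates of experiment 2 held 7 and 9 naive cells. The turn of Polh with averages per plate rests on the same indirect comparison. The split was 64 and 55 on the deposited scale and 8 and 30 after thinning. Without the anti-PD1 mouse of experiment 1 and mice 1 and 2 of experiment 2 the calls were 49, 51 and 53, and they were 0 without experiment 2.

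The comparison of conditions within IgG1 GC cells asked whether cells of the same sort differed after anti-PD1. No gene passed, and Mcm2 and Ubec2c had the smallest p-values. Mcm2 held 1.56% ± 0.313 of the panel total with anti-PD1 and 1.16% ± 0.399 at steady state (SD, n = 3 each), a difference of 0.56 ± 0.11 (SE) with limma's adjusted p = 0.109. Ubec2c held 1.06% ± 0.0159 and 0.660% ± 0.0856 (SD, n = 3 each), with adjusted p = 0.140 by limma. Mki67 differed by 0.46 ± 0.21 (SE) and Top2a by 0.35 ± 0.15 (SE), and all genes named for this comparison were chosen after their values were seen. The GC regulators Aicda (0.15 ± 0.13, SE) and Bcl6 (0.09 ± 0.08, SE) and the class II chain H2-Aa (−0.31 ± 0.28, SE) did not pass either.

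Of 257 genes, limma called 0 higher and 0 lower, and 17 had an unadjusted p under 0.05. The 95% interval of a gene's difference reached a median of 0.21 to either side. In 22 genes all 3 anti-PD1 mice lay above all 3 steady-state mice and in 1 gene below. Chance gives 10% of genes in either direction, but only where genes enter alike through both groups. The filter was met by 254 genes with anti-PD1 and 207 at steady state. The 6 tested proliferation genes had a median difference of 0.37, and 1 was higher when adjusted over the list alone. Their fry adjusted p was 0.202, and camera's was 0.00193, or adjusted p = 0.243 with an estimated correlation. Camera also passed checkpoint and class II genes with its preset correlation, at 0.0102 and 0.0386, with adjusted p = 0.243 and 0.335 with an estimated correlation. Fry passed 0 of 19 lists. On the deposited scale 28 genes were higher and 0 lower, while thinning called 0 higher and 1 lower, Tnfrsf13c, weights by number of cells called 7 and the log2 of the mean value called 0. Splitting the anti-PD1 mouse of experiment 1 by plate letter called 2, Mcm2 and Ubec2c, and leaving out any mouse or experiment called 0.

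For plasma cells, only 17 IgG1 cells came from steady-state mice, and 1 mouse reached the required 10. Under that rule IgG1 plasma cells were not tested between conditions. Anti-PD1 IgG1 plasma cells were compared with steady-state plasma cells that were not IgG1, so condition and isotype differed together. Against steady-state plasma cells of any isotype, 18 genes were higher and 3 lower, and 13 of these 21 were among the 18 called below. Mki67, Mcm4, Top2a and Mcm2, genes of dividing cells, were among those higher in the anti-PD1 IgG1 cells. Mki67 (chromosome 7, 135689784 to 135716450) held 1.11% ± 0.30 of the panel total against 0.425% ± 0.174 (SD, n = 3 each), a difference of 0.95 ± 0.21 (SE) with limma's adjusted p = 0.0222. Ubec2c, a panel name that matched no mouse symbol, held 0.936% ± 0.0901 against 0.164% ± 0.165 (SD, n = 3 each), with adjusted p = 0.000427 by limma. Mcm4, Top2a and Mcm2 were higher by 0.88, 0.64 and 0.55. Cd24a held 5.59% ± 1.29 against 3.23% ± 1.31 and Mzb1 16.1% ± 1.82 against 9.86% ± 3.03 (SD, n = 3 each). Prdm1, which encodes the plasma cell regulator Blimp-1 (chromosome 10, 44437174 to 44528558), held 0.349% ± 0.130 against 1.01% ± 0.471, and Cd79a, a chain of the antigen receptor (chromosome 7, 24897497 to 24901858), 0.369% ± 0.144 against 2.15% ± 1.25 (SD, n = 3 each).

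Among 251 genes, 12 were higher and 6 lower. All 18, called from these same averages, had the same direction in both experiments. The values of single mice overlapped between the groups in Mcm2 and Klf7. Over all 251 genes, the 3 anti-PD1 values lay above the 3 steady-state values in 28 and below in 14. Chance gives 10% of genes in either direction, but only where genes enter alike through both groups. The filter was met by 246 genes in the anti-PD1 cells and 178 in the 69 steady-state cells. The other genes higher were Slpi (0.84), the mitochondrial pyruvate carrier Mpc2 (0.92), Klf7 (0.33) and, chosen after their values were seen, Lef1 and Slamf6, both listed at 0 in the steady-state cells. Deposited totals were 173 to 309 units in those cells and 556 to 770 in the anti-PD1 cells, so a listed 0 may hide a low value. The other genes lower were Ly6c1 (−0.60), the cytokine receptor chain Il2rg (−0.42), Cited2 (−0.29) and Foxo3 (−0.17). Of 6 proliferation genes, 3 were higher and 0 lower, or 5 when adjusted over the list alone. This was the 1 list of 21 that fry passed, with adjusted p = 0.0126, and camera gave adjusted p = 0.360 with an estimated correlation. Of 16 plasma cell markers 2 were higher, Mzb1 and Slpi, and 2 lower, Ly6c1 and Prdm1. Secretion, class II, light zone and checkpoint genes had 0 calls among 5, 7, 11 and 9 tested. The difference between the plasma cell and the GC comparison was tested as an interaction, and 0 of 300 genes passed in limma (23 with an unadjusted p under 0.05). It gave 7 calls on the deposited scale, 1 with weights by number of cells, 0 with the log2 of the mean value or thinning, and 4 without mouse 3 of experiment 2. The split was 82 higher and 3 lower on the deposited scale, 5 and 5 with the log2 of the mean value, and 2 and 0 after thinning, Ubec2c and Mzb1. With only the compared groups in the fit 0 genes passed, at a smallest adjusted p of 0.0904 by limma. The 18 calls thus depend on the spread and the experiment block taken from all 7 groups of cells. All 18 kept their direction, which is almost fixed, since the averages compared were the same. Calls fell to 2 without the anti-PD1 mouse of experiment 1, to 3 without mouse 2 of experiment 2 and to 0 without either experiment. With the plate as a block 15 of the 18 genes were called, and 16 of 18 went the same way on each of the 4 plates. Both counts reuse the cells that gave the calls.

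**Figure D3:**
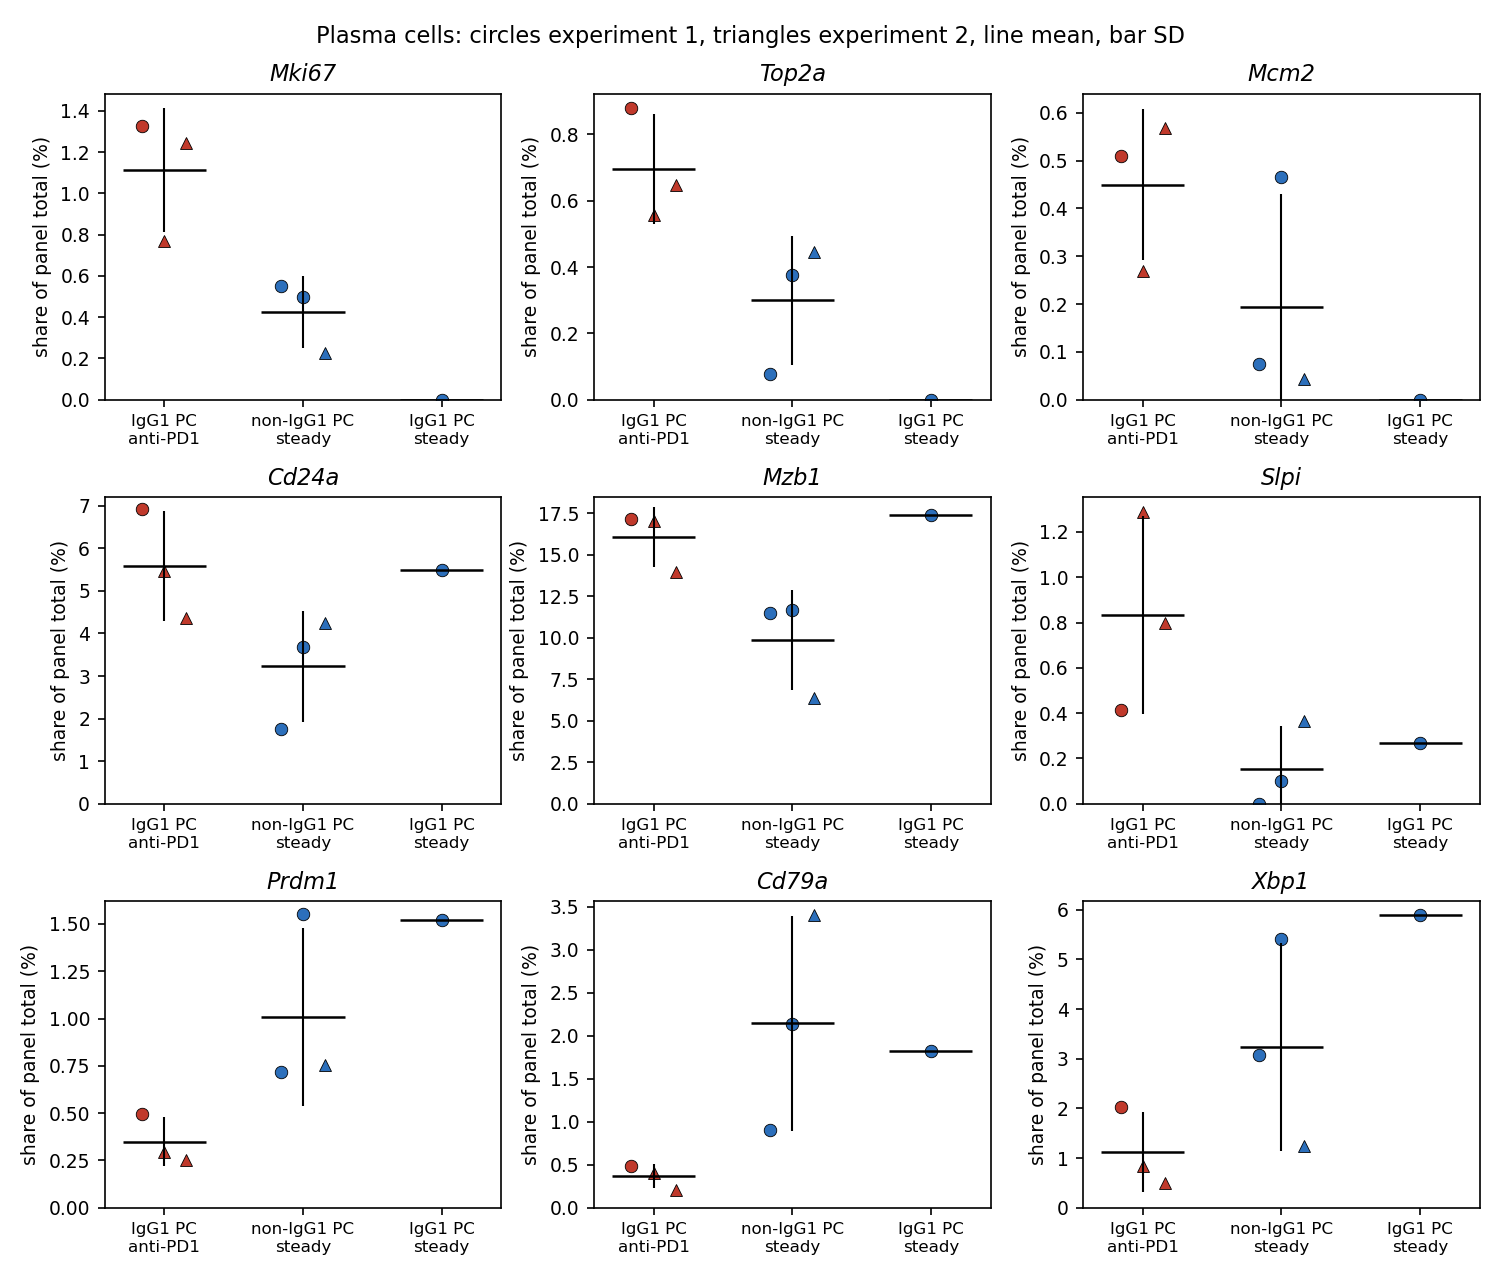
Share of the panel total (vertical axes, percent) of single genes in plasma cells, by condition and isotype (horizontal axis); points are mice, lines are the mean and SD over 3 mice, and the steady-state IgG1 group is 1 mouse of 11 cells without SD. SD bars that would reach below 0 end there. Mki67 held 1.11% in anti-PD1 IgG1 cells and 0.425% in steady-state cells that were not IgG1.

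The panel did not hold Pdcd1, so only the ligands of PD-1 could be read. Cd274, which encodes the ligand PD-L1, had a nonzero value in 22 of 180 anti-PD1 IgG1 plasma cells (12.2%, exact interval 7.82 to 17.9%) and in 6 of 69 steady-state plasma cells that were not IgG1 (8.70%, 3.26 to 18.0%). It was nonzero in 7 of 300 anti-PD1 IgG1 GC cells (2.33%, 0.943 to 4.75%), in 0 of 248 at steady state (up to 1.48%) and in 0 of 158 naive cells (up to 2.31%). Deposited totals had medians of 723 units in the anti-PD1 plasma cells and 77.5 in naive cells, so shares of cells could not be compared between labels. On the common total, Cd274 differed by −0.06 between the plasma cells of the conditions, with limma's adjusted p = 0.749. Pdcd1lg2, which encodes the other ligand, was nonzero in 11 of 300 anti-PD1 and 5 of 248 steady-state IgG1 GC cells, too few to be tested.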

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

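The tests in this part were planned before their results were seen. Steady-state GC cells that were not IgG1 (75 cells of 1 mouse) took 7.38% of the panel total in GC markers, above the highest naive value of any mouse (3.88%). The 17 steady-state IgG1 plasma cells took 30.1% in plasma cell markers, where naive cells of any mouse took at most 2.14%. Both groups drew attention as signals above naive cells in cells left out of the report's main comparisons. They had been sorted as GC or plasma cells, so these values are no independent test. The naive cells came from anti-PD1 mice only, and both groups from steady-state mice. The summed share of the GC markers does not set GC cells apart from plasma cells, although fry passed the list as lower in anti-PD1 IgG1 plasma than GC cells (adjusted p = 8.06e-06). It took 6.21% ± 1.29 in anti-PD1 IgG1 GC cells, 5.52% ± 0.555 in anti-PD1 IgG1 plasma cells and 7.16% ± 1.44 in steady-state plasma cells that were not IgG1 (SD, n = 3 each), and 9.73% over the 17 steady-state IgG1 plasma cells. Groups of 3 mice were not tested for single outlying mice.

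Naive-sorted cells held plasma cell transcripts, with 1.60% ± 0.469 (SD, n = 3) of the panel total in plasma cell markers. Carry-over from plasma cell wells of the same plate would place more of them in naive cells on plasma cell plates than on GC plates. The median ratio over 4 pairs of plates was 1.12, with single ratios of 1.33, 1.10, 1.13 and 0.955, which argues against carry-over within a plate as the whole source. Mzb1, singled out after its values were seen, took 1.59% on the plasma cell plate against 1.39% on the GC plate and 0.954% against 1.21% in experiment 1, and 1.18% against 0.483% and 0.694% against 0.469% in experiment 2, where the plasma cell plates held 7 and 9 naive cells. Carry-over as a part of the Mzb1 in naive cells therefore stays open. A level that is alike on every plate, by expression in naive cells or by carry-over that does not depend on the plate, could account for the same ratio of 1.12. No biological explanation was tested.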

How the results depend on the processing

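Thinning, the random block for the mouse, averages per plate, weights, fits of only the compared groups, the split of 1 mouse and the omission of single mice were chosen after the totals were seen. The number of IgG1 GC genes called between conditions, 0, became 12 with the share of cells with a nonzero value, 28 as deposited, 1 thinned, 7 with weights by number of cells and 2 with the anti-PD1 mouse of experiment 1 split by plate letter. It was 0 whichever mouse or experiment was left out. For plasma cells between conditions the 18 calls became 10 with the log2 of the mean value, 31 with pseudocount 0.1, 81 with the share of cells, 85 as deposited, 2 thinned and 0 with only the compared groups, and 0 to 21 with a mouse or experiment left out. For GC against naive cells the 66 calls became 40 with the log2 of the mean value, 106 with pseudocount 0.1 (102 higher and 4 lower), 169 with the share of cells, 149 as deposited and 26 thinned, and 0 to 69 with a mouse or experiment left out. For plasma against naive cells the 80 became 167 with the share of cells, 172 as deposited and 45 thinned, and 0 to 91 with omissions. For plasma against GC cells the 94 became 38 thinned and 54 with the plate as a block (compared only through naive cells), and 0 to 102 with omissions. The interaction, with 0, gave 5 with the share of cells, 7 as deposited, 1 with weights and 0 to 4 with omissions.

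Gene lists past fry went from 0 to 7 (GC cells between conditions), 1 to 16 (plasma cells between conditions), 10 to 18 (GC against naive) and 11 to 18 (plasma against naive) with the share of cells. Of the lists past fry, the share of cells turned naive markers and trafficking receptors from lower to higher in GC against naive cells, both past fry again. In plasma against naive cells it turned the B cell receptor and housekeeping lists, past fry again, and naive markers, trafficking receptors and class II genes, no longer past it. In plasma against GC cells it turned cytokines and receptors, with adjusted p = 0.800. Without the member of the largest difference they went from 10 to 6 for GC against naive and from 14 to 8 for plasma against GC cells. The 7 clusters became 4 at resolution 0.25 and 4 to 5 with 1 experiment alone.

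Over the 140 results of named genes, 3217 values under other settings were computed: 2572 had the same direction and call, 626 lost the call and 19 reversed. The share of cells with a nonzero value reversed Prdm1 in plasma cells between conditions (3.69 points), H2-K1 in GC against naive cells (2.66), and Tgfb2 in plasma against GC cells (1.97). In plasma against naive cells it reversed H2-DMb2 (9.39), Cd79b (8.20), Ptprc (6.09), Tnfrsf13c (19.1) and S1pr1 (0.809). The deposited scale reversed H2-K1 in GC against naive cells (0.78), and in plasma against naive cells Cd74 (0.23), Cd79a (0.031), H2-DMb2 (0.088), Cd79b (0.65), Ptprc (0.069) and Tnfrsf13c (0.57). Tnfrsf13c in GC against naive cells was at −0.22 with the log2 of the mean value and −0.020 thinned, Ccnd2 in plasma against naive cells at −0.070 with the log2 of the mean value, and Polh in plasma against GC cells at −0.0097 with the plate as a block. Both the deposited scale and the share of cells follow each label's own total, which moves the genes of a comparison together, so these turns do not show a gene's direction. For the other changes the cause was not tested. Without experiment 2, where 1 residual degree of freedom was left, all 137 calls among the 140 were lost (the other 3 are Cd274, named whatever its values), and with thinning, which leaves fewer units per cell, 61 were. The random block for the mouse changed 0 of 140. Clustering without immunoglobulin genes and classes from the sort gate genes were not run, since the panel held no immunoglobulin gene. With the mouse as a fixed block, the paired form of the comparisons within mice, which was added after all other results were seen, GC against naive cells gave 50 calls, 46 of the 66 among them, plasma against naive cells 84 with 76 of the 80, and plasma against GC cells 85 with 77 of the 94. It called 0 genes for the interaction, and 9 of 123 named-gene results lost the call, with 0 reversed. They were Pparg, Ly6d, Tnfrsf13c, Icam1, Itgb1 and Blnk in GC against naive cells, Tnfsf9 in plasma against naive cells, and Gzma and Tgfb2 in plasma against GC cells. Lists past fry were 8, 9 and 11 for 10, 11 and 14, and no other call of a list or named gene changed.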

Other observations

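The tests of the scaling, of total RNA and of the plates in this part were chosen after the result was seen. The 1 steady-state mouse with at least 10 IgG1 plasma cells had 11, which are given as values without a test. Their averages were listed at 0 for Mki67, Pcna, Mcm4, Ubec2c, Top2a and Mcm2, and proliferation genes took 0.142% of the panel total, against 4.15% ± 1.12 (SD, n = 3) in anti-PD1 IgG1 plasma cells. Deposited totals were 140 to 208 units in these 11 cells and 556 to 770 in the anti-PD1 IgG1 plasma cells. A median of 29 genes per cell was nonzero in the 11 cells, so a listed 0 may hide a low value. Xbp1 took 5.89% against 1.12% ± 0.804 (2.03% in the anti-PD1 mouse of the same experiment), Pou2af1 7.81% against 2.35%, Ell2 2.25% against 0.433% and Prdm1 1.52% against 0.349%, while Mzb1 took 17.4% against 16.1% ± 1.82. Of these 11 cells 9 lay on 1 plate, plasma cell plate B of experiment 1, so plate and group are mixed in these values of Xbp1, Pou2af1 and Ell2. On that plate, Xbp1 took 6.91% in its 11 steady-state IgG1 plasma cells (of 2 mice), 6.16% in 28 steady-state cells that were not IgG1 and 2.46% in 55 anti-PD1 IgG1 cells. On plate A of experiment 1 it took 1.41% in 3, 2.93% in 18 and 1.46% in 41 cells in the same order, and there the 3 steady-state IgG1 cells were below the anti-PD1 cells in Pou2af1 (1.58% against 3.45%) and Ell2 (0.310% against 0.435%). On plate B of experiment 2 the 3 steady-state IgG1 cells were above the 30 anti-PD1 cells in Xbp1 (2.06% against 0.842%), Pou2af1 (2.55% against 2.05%) and Ell2 (0.309% against 0.240%). Prdm1 was higher in steady-state than in anti-PD1 IgG1 cells on each of the 3 plates, by 2.17% against 0.425% and 1.88% against 0.549% on plates A and B of experiment 1 and 1.40% against 0.296% on plate B of experiment 2. Mzb1 took 20.4% in steady-state against 16.8% in anti-PD1 IgG1 cells on plate A and 15.4% against 17.4% on plate B of experiment 1. On plate B of experiment 2 it took 8.76% against 17.1%. Mki67 was listed at 0 in all 17 steady-state IgG1 plasma cells, on 3 plates. Of the 18 genes called between anti-PD1 IgG1 and steady-state plasma cells that were not IgG1, 13 had the same direction against these 11 cells. Mzb1 (−0.08), Mpc2 (−0.29), Il2rg (0.10), Cited2 (0.10) and Foxo3 (0.10) turned. Most genes with values here were higher in the anti-PD1 cells, many of them from 0, and both comparisons share the anti-PD1 cells. The 13 are therefore no independent support for the calls. In the 75 steady-state GC cells that were not IgG1, the unfolded protein response kinase gene Eif2ak3 took 1.13% against 0.0408% ± 0.037 in steady-state IgG1 GC cells (SD, n = 3), and Foxj1 0.366% against 2.19% ± 2.04. The 75 cells were all of experiment 1, and 2 of the 3 compared mice of experiment 2, where Foxj1 was higher. They lay on GC plate B, while the compared IgG1 GC cells of experiment 1 came from another mouse on GC plate A. Isotype, mouse and plate are therefore mixed in these values, also within experiment 1. The difference of Foxj1, IgG1 minus not IgG1, was 1.58 on the log2 scale over all mice and 0.97 within experiment 1. These genes were chosen after their values were seen.

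Of 7 clusters, cluster 3 (173 cells) and cluster 6 (87 cells, all of experiment 1) held mostly plasma cells, with 14 and 15 of 17 plasma cell markers higher than in other cells. Cluster 4 held 151 cells, 130 of them naive. GC cells split by experiment: of the anti-PD1 IgG1 GC cells, 153 of 159 in experiment 1 and 6 of 141 in experiment 2 were in cluster 1. Between experiments, Actb was lower in experiment 2 in each of 5 groups by 0.92 to 1.95 log2, and Spp1 and Xcl1 were higher, by 0.75 to 1.15 and 0.65 to 1.04. These 3 genes were chosen after their values were seen. On plasma cell plate B of experiment 1, cluster 6 held 46 of 55 anti-PD1 IgG1 cells, 11 of 11 steady-state IgG1 cells and 28 of 28 that were not IgG1, while on plate A all 41, 3 and 18 were in cluster 3. T cell markers took 1.26% ± 0.868 of the panel total in anti-PD1 IgG1 plasma cells (0.329 to 2.05% by mouse), 0.841% ± 0.856 in steady-state plasma cells that were not IgG1, 1.05% ± 0.511 in naive cells, and 0.616% ± 0.175 and 0.621% ± 0.124 in anti-PD1 and steady-state IgG1 GC cells (SD, n = 3 each).

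On the deposited scale 28 IgG1 GC genes were higher with anti-PD1 and 0 lower. After rescaling to a common total 0 were, which the authors' scaling of each sort label to its own total could account for. Whether cells also held more RNA after anti-PD1 stays open, since 98.0% of the variance of the log2 totals lay between labels, and the totals were set per label.

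More genes were higher than lower in IgG1 GC than in naive cells, 60 against 6. With the plate as a block 89.7% of the calls were higher, which argues against a difference between plates. With every cell thinned to the same total 65.4% were, so that the coarser rounding of naive cells may add to the excess, and the test does not decide how much. The filter on nonzero values, met by 254 genes in GC cells and 106 in naive cells, also let most genes in through GC cells alone.

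Each comparison of 3 with 3 averages allows 10 splits, too few for a share under 0.05. In the comparisons of classes both sides came from the same 3 anti-PD1 mice. The splits ignored this pairing, so their counts do not test the paired form of these comparisons. For IgG1 GC cells between conditions 10 of 10 splits had at least the real 0 calls, and the highest other had 2. For the others 1 of 10 splits, the real one, had as many: plasma cells between conditions 18 with the highest other at 14, GC against naive 66 and 0, plasma against naive 80 and 1, and plasma against GC 94 and 0. The split with 14 was that of experiment 1 against experiment 2, and both counts come from fits with the experiment as a block. The block, shared by all groups of cells, did not remove these 14. Anti-PD1 cells came from 1 mouse of experiment 1 and 2 of experiment 2, and steady-state cells from 2 and 1. Condition and experiment thus partly overlap, and differences between experiments may enter the 18 calls. How far they do was not tested. All 18 had the same direction in both experiments, but they were called from these same averages, so this is no separate test.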
